A study of Mus musculus with 2 samples.

How the data were processed

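The series holds 2 samples of mouse lens at embryonic stage E12.5, 1 of lens epithelium and 1 of lens fibers, both described as wild type. Per the labels' protocols, total RNA was isolated with a column kit, labelled with biotin and hybridised to Illumina arrays, and the probe annotation is that of a 1-colour Illumina expression array for the whole mouse genome. How the epithelium and the fibers were separated, how many embryos were pooled and which strain was used are not given in the sources used here.

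The authors deposited 1 intensity per probe and array, on a linear scale, for 45281 probes. Every deposited intensity was a whole number, the lowest was -16 on both arrays, and 38.0% of the epithelium values and 38.7% of the fibers values were at or below 0, so a background had been subtracted before deposit. How the background, any scaling between arrays and the rounding were done is not given in the sources used here. The deposited values had medians of 5 (epithelium) and 4 (fibers), 95th percentiles of 142 and 139, and highest values of 36428 and 24408.

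All choices below were fixed before the data were examined unless stated otherwise. Values were to be used as deposited if the percentiles of the arrays from the 10th to the 99th differed by under 0.1 on the log2 scale. Only percentiles from the 39th upward were positive on both arrays, and their largest difference was 0.58, at the 45th percentile, so the arrays were quantile normalized on the linear scale. From the 75th to the 99th percentile the difference was 0.05 or less. Quantile normalization gives both arrays the same distribution, so a difference in total RNA content between the tissues cannot be seen.

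Probes were named through the platform annotation: 34885 probes had 1 gene symbol, 18 had several and 10378 had none and are unnamed here. The gene ID of 34807 of the named probes was found in the reference gene table and that of 78 was not. The named probes covered 19057 genes, of which 9172 had several probes. A gene was represented by its brightest probe over both arrays. This rule favours probes that also bind other transcripts, and disagreement between probes is reported. Probe sequences and genome positions were not used here.

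The floor of each array was the 95th percentile of 1580 probes for 1308 genes taken to be silent in lens (olfactory, vomeronasal and trace amine receptors and keratin-associated proteins). It was 44.6 on the epithelium array and 32.1 on the fibers array. A gene above the floor on both arrays has a log2 ratio of fibers over epithelium. A gene above the floor on 1 array only has a bound, the bright value over the floor of the other array, written "at least N-fold". For 788 genes the bound lay under 1, because the floors differ, and no direction was given. Genes below the floor on both arrays have no ratio.

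With 1 array per group there were no replicates, so no test, p-value, standard error or SD between replicates was computed, and the number of arrays limits the precision. Each ratio describes these 2 arrays. The spread available was that of 32 silent probes above the floor on both arrays and of probes of the same gene. No batch or slide information was used here.

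The comparison was described by counts of genes at a 2-fold difference and by 21 gene lists and 7 lists of markers of other cell types, together 438 genes, of which 38 had no named probe and 16 were in more than 1 list. The gene lists covered crystallins, fiber genes, lens epithelium genes, lens transcription factors, mitosis, DNA replication, cell cycle inhibitors, FGF, BMP and TGF-beta, Wnt and Notch signalling, basement membrane, autophagy, glycolysis and hypoxia, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, chromatin regulators, RNA-binding proteins, immediate early genes and housekeeping genes. The median log2 ratio of each list with at least 3 measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A bound enters a median at its value, but a gene whose bound lay under 1 enters as a log2 ratio of 0. This holds for the random lists too, so a list median of 0.00 can stand for genes with no direction. A list was said to stand apart when its percentile was below 2.5 or above 97.5. The percentile describes these arrays and is not a test of the tissues.

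The genes named in the text follow a fixed rule. It takes the 10 highest and 10 lowest ratios among genes on both arrays and the 5 largest bounds per direction. It adds all measured crystallins and lens transcription factors, and up to 4 members with the largest absolute log2 ratio from every other list. It also adds any list member that differs by 2-fold or more against its list's median direction. Other genes are said to be chosen after their values were seen.

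In all, 10 alternatives were planned for the counts, list medians and named genes. They were the values as deposited, arrays centred on their medians, a loess fit with span 0.4, floors at the 60th and 75th percentile of all probes and no floor, subtraction of the silent probes' median, an offset of 50, the mean of all probes, and the second brightest probe. A gene with a single probe keeps its value under the mean of all probes and under the second brightest probe. Thresholds of 1.5-fold and 4-fold and a crystallin list without Cryga to Crygf were also planned. A scaling to housekeeping genes and a common floor (the higher of the 2) were added after seeing the data.

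The calculation was tested on simulated values for this comparison over 19057 genes, with noise of SD 0.3 on the log2 scale. The changed genes were drawn only from bright genes above the floor on both real arrays. Of 50 genes changed per size, 58% of those changed 2-fold and 98% of those changed 4-fold were called in the right direction at 2-fold. So were 100% of those changed 8-fold or 16-fold, against 1.69% of 5315 unchanged genes. Recovery was not tested for dim genes or for genes above the floor on 1 real array only. Of 200 random lists of 12 genes, 6 lay outside the percentiles 2.5 to 97.5, and 20 of 20 shifted lists, drawn from the same bright genes, lay above 97.5. The noise between the real arrays was larger than the simulated noise. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.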

Results

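Gene expression was measured in 2 parts of the embryonic mouse lens at embryonic stage E12.5, the epithelium at the front and the elongating fibers behind it, with 1 array for each. The deposited intensities of 45281 probes had a Pearson correlation of 0.87 and a Spearman correlation of 0.71 across probes, which are not independent replicates. After quantile normalization, 6490 of 19057 genes were above the floor on at least 1 array. Of these, 2980 were above it on both arrays, 2357 on the fibers array only and 1153 on the epithelium array only. The excess on the fibers array depended on its lower floor. With the common floor, 1545 genes were above it on the fibers array only and 1514 on the epithelium array only. All intensities below are normalized, and all log2 ratios are fibers over epithelium.

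The comparison asked which transcripts differ between the epithelium and the fibers of the wild-type lens. Crystallins, the abundant soluble proteins of the lens, and genes of the fiber cell membrane and cytoskeleton were higher in fibers, with list medians of 7.33-fold and 6.20-fold. DNA replication and mitosis genes were higher in epithelium, with list medians of at least 3.55-fold and at least 2.28-fold. Both medians fell on bounds, which made up 10 of 13 and 9 of 12 measured members. Among the fiber genes, 9 of 13 measured members had a bound. Autophagy genes had a median of at least 2.17-fold higher in fibers, with bounds for 8 of 12 measured members. Housekeeping genes were also higher there (1.62-fold). Scaled to housekeeping genes, the autophagy median was 0.51 on the log2 scale, with 2 of 12 genes at 2-fold or more. Of the 6490 measured genes, 1006 were higher in fibers by 2-fold or more (426 on both arrays, 580 as bounds) and 1186 were higher in epithelium (516 on both arrays, 670 as bounds).

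**Figure D1:**
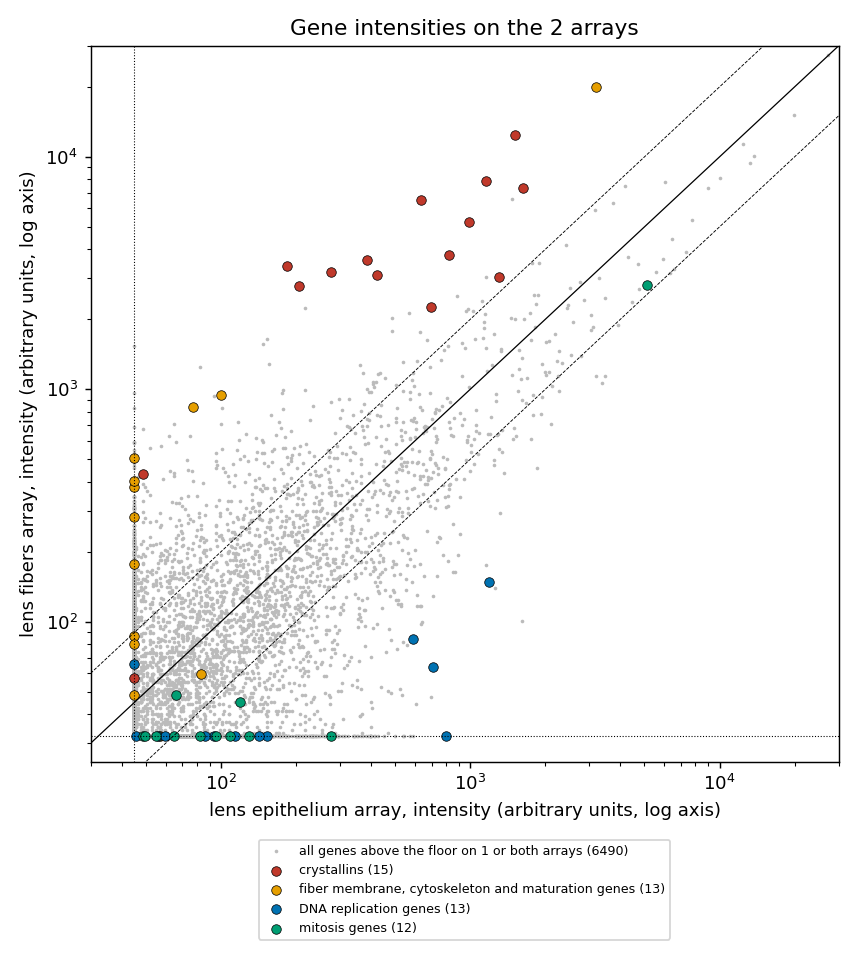
Normalized intensity of each gene on the epithelium array (horizontal, arbitrary units, log axis) and on the fibers array (vertical, arbitrary units, log axis), with values below a floor drawn at the floor (dotted lines), the line of equal intensity (solid) and 2-fold differences (dashed). Each point is 1 of 6490 genes. Of these, 14 of 15 crystallins lie above the upper dashed line and 9 of 13 DNA replication genes lie beyond the lower one, with no replicate arrays. The 788 genes with no direction lie below the solid line only because the floors differ.

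Of 15 measured crystallins, 14 were higher in fibers by 2-fold or more and none was higher in epithelium, and the median log2 ratio of 2.87 lay at percentile 100 of random lists. Crybb1, a beta crystallin (probe ILMN_2702122), had the highest ratio of all genes measured on both arrays, 183 in epithelium and 3389 in fibers (18.5-fold). Crygc, a gamma crystallin, read 207 and 2788 (13.5-fold), and Cryaa, the alpha A crystallin, which is also a small heat shock protein, read 276 and 3183 (11.5-fold). Cryba4, a beta crystallin, read 1512 and 12383 (8.19-fold). The other beta and gamma crystallins, Crybb3, Crygf, Crygs, Crygn, Crygd, Cryba1, Cryge, Crygb, Cryba2 and Cryga, ran from 10.3-fold for Crybb3 to 2.32-fold for Cryga. Cryab, the alpha B crystallin, was above the floor on the fibers array only, at 57.2, at least 1.28-fold higher. The list without the near-identical Cryga to Crygf had a median of 3.03.

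Crystallins also gave signal in epithelium. Over the 14 crystallins above the floor on both arrays and Mip, the water channel of the fiber membrane, which was chosen after its values were seen, the epithelium signal was a median of 13.6% of the fibers signal, from 5.41% for Crybb1 to 43.1% for Cryga. For 13 genes at 500 or more on the fibers array and below the floor in epithelium, that share was at most 2.91% (Chrng) to 8.82%.

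Of 13 measured fiber membrane, cytoskeleton and maturation genes, 8 were higher in fibers by 2-fold or more and none was as much higher in epithelium (median log2 ratio 2.63, percentile 100). Grifin, a galectin-related protein of the lens, read 77.3 in epithelium and 837 in fibers (10.8-fold), and Ank2, an ankyrin that links the membrane to spectrin, read 99.8 and 941 (9.43-fold). Tdrd7, a component of RNA granules, was at least 11.3-fold higher in fibers and Caprin2, an RNA-binding protein, at least 9.04-fold. Mip read 3206 and 19878 (6.20-fold). The membrane protein gene Lim2 was at least 8.54-fold higher, while Cdh2, N-cadherin, had a log2 ratio of -0.49 and Lctl a bound of -0.82. Lim2, Cdh2 and Lctl were chosen after their values were seen.

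**Figure D2:**
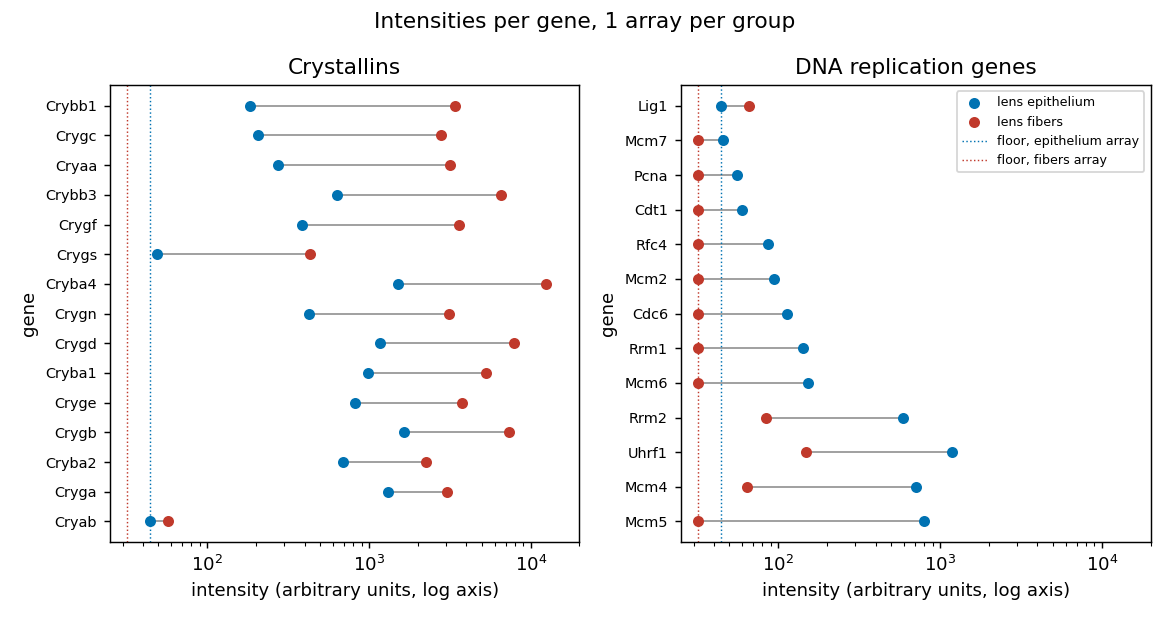
Normalized intensity (horizontal, arbitrary units, log axis) of the measured crystallins (left panel) and DNA replication genes (right panel) in lens epithelium (blue) and lens fibers (red), 1 array per group, with values below a floor drawn at that floor (dotted lines). All 15 crystallins have the fibers point to the right, and 12 of 13 replication genes have the epithelium point to the right, the exception being Lig1.

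Of 13 measured DNA replication genes, 9 were higher in epithelium by 2-fold or more and none was as much higher in fibers (median log2 ratio -1.83, percentile 0). Mcm4 and Mcm5 encode subunits of the replicative helicase. Mcm4 read 707 in epithelium and 64.1 in fibers (11.02-fold), and Mcm5 read 800 in epithelium and was at least 24.9-fold higher there. Uhrf1, which couples DNA methylation to replication, read 1194 and 149 (8.02-fold), and Rrm2, a subunit of ribonucleotide reductase, read 590 and 84.5 (6.98-fold). Lig1, a DNA ligase chosen after its values were seen, was the only member with a positive log2 ratio, 0.56, a bound, and it had no direction when scaled to housekeeping genes.

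All 12 measured mitosis genes had negative log2 ratios, 7 of them by 2-fold or more (median -1.19, percentile 0.02). Plk1, a mitotic kinase, read 277 in epithelium and was at least 8.62-fold higher there. The spindle motor Kif11 was at least 4.04-fold higher in epithelium, the ubiquitin-conjugating enzyme Ube2c at least 3.38-fold and the mitotic kinase Aurka at least 2.96-fold. For 9 of the 12 the ratio was a bound, which cannot be positive for a gene above the floor on the epithelium array only. All 12 were negative under each scaling, which for those 9 is no check of the direction.

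Of 8 cell cycle inhibitors, 3 were higher in fibers by 2-fold or more and 1 in epithelium (median 0.90, percentile 95.2), against 1 and 2 when scaled to housekeeping genes. The list stood apart with no floor (percentile 97.6) and with the mean of all probes (percentile 97.8), and under none of the other alternatives. Cdkn1c, the cyclin-dependent kinase inhibitor p57, read 391.9 in epithelium and 972 in fibers (2.48-fold). Ccng1, cyclin G1, was at least 4.34-fold higher in fibers and Rb1, the retinoblastoma protein gene, at least 2.10-fold. Btg1, an antiproliferative gene, went the other way, 642 and 99.3 (6.47-fold higher in epithelium).

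Of 15 chromatin regulators, 3 were higher in fibers and 4 in epithelium by 2-fold or more (median 0.00, percentile 38.9), against 0 and 5 when scaled to housekeeping genes. Dnmt1, the maintenance DNA methyltransferase, read 868 in epithelium and 164 in fibers (5.30-fold). Ezh2, the histone methyltransferase of the Polycomb complex PRC2, was at least 4.31-fold higher in epithelium, and Hdac2, a histone deacetylase, was 2.80-fold higher there. The acetyltransferase gene Ep300 was at least 2.82-fold higher in fibers.

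Among 9 measured lens epithelium genes, 5 were higher in epithelium by 2-fold or more and 3 in fibers (median -1.18, percentile 1.21), against 5 and 1 when scaled to housekeeping genes. The call ended under 5 of 12 alternatives. With the second brightest probe the median was 2.09, in the opposite direction, over the 5 genes still measured, each of which kept the sign of its log2 ratio. Gja1, the gap junction protein connexin 43, read 399 in epithelium and was at least 12.4-fold higher there. Cdh1, E-cadherin, read 854 and 164 (5.22-fold), and Pdgfra, a growth factor receptor, read 426 and 155 (2.74-fold). The members higher in fibers were Dkk3 (4.74-fold) and Sfrp1 (2.70-fold), both secreted proteins related to Wnt modulators, and the laminin receptor subunit Itga6 (2.34-fold).

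Of 14 measured lens transcription factors, 3 were higher in fibers by 2-fold or more and 5 in epithelium (median 0.00, percentile 52.9), against 1 and 6 when scaled to housekeeping genes. Mafg, a small Maf factor, read 118 in epithelium and 603 in fibers (5.12-fold), and Prox1, a homeobox factor of fiber differentiation, read 632 and 1758 (2.78-fold). Hsf4, a heat shock factor of the lens, was at least 3.05-fold higher in fibers, and Maf at least 1.57-fold. Pax6, the paired-box regulator of eye development, read 195 in epithelium and 69.1 in fibers (2.82-fold), and Mab21l1 was 3.29-fold higher in epithelium. The bounds in favour of epithelium were at least 5.04-fold for Sox11, 3.02-fold for Pitx3 and 2.57-fold for Tfap2a, and a second Sox11 probe had no direction. Zeb2 had a log2 ratio of -0.91, with a second probe at 0.60, and Meis2 had 0.45, which was -0.14 when the arrays were scaled to housekeeping genes. Six3, Meis1 and Etv5 were above the floor on the fibers array only, with no direction. The list median of 0.00 fell on these genes, which enter it as 0.

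Markers of other cell types were mostly below the floor. Tfap2b, a marker of periocular mesenchyme, read 209 in epithelium and 36.2 in fibers (5.76-fold), and Sfrp2, a marker listed for retina and also a secreted Wnt modulator, read 1256 and 140 (8.99-fold). Both lay in the direction of the lens epithelium, DNA replication and mitosis lists, and each was the only measured member of its marker list, of 12 and 10 genes on the array. The pigment cell list held Pmel (log2 ratio -0.80, a bound) and Mitf (0.27), the surface ectoderm list Krt5 (0.42), and the endothelium list Tek (0.90, a bound). Mitf and Krt5 were at -0.33 and -0.19 when the arrays were scaled to housekeeping genes. The erythroid list held the embryonic globin Hbb-y, at 121 in epithelium and 124 in fibers, and Hba-a1 (0.78, a bound). The brighter globin Hbb-bs, outside the list by its name and chosen after its values were seen, read 3458 in epithelium and 2458 in fibers, and its second probe read 346 and 53.3 (6.49-fold), in the direction of the epithelium lists. Another globin outside the list, Hbb-bt, was at least 4.41-fold higher in epithelium, with a second probe above the floor on the fibers array only. The macrophage list held Aif1 (-0.68) and Csf1r, which had no direction.

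Of 8 Wnt signalling genes, 4 were higher in fibers and 2 in epithelium by 2-fold or more (median 1.18, percentile 99.9). The ligand gene Wnt7b read 888 in epithelium and 2517 in fibers (2.83-fold), and the transcription factor Tcf7l2 was at least 2.78-fold higher in fibers. Dkk3 and Sfrp1, given above, were the other members higher in fibers by 2-fold or more. Sfrp2 and Wnt5a, a ligand at least 2.43-fold higher in epithelium, went the other way. The call ended under 5 of 12 alternatives, and the median was 0.00 with no floor. Scaled to housekeeping genes, 1 member was higher in fibers and 3 in epithelium by 2-fold or more.

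Of 4 Notch genes, 2 were higher in fibers and none in epithelium by 2-fold or more (median 0.67, percentile 96.8), against 1 and 1 when scaled to housekeeping genes. The list stood apart under 3 of 12 alternatives. The ligand gene Jag1 read 117 and 721 (6.17-fold), the target gene Hey1 was at least 2.54-fold higher in fibers, the coactivator Maml1 had a bound of -0.82, and Lfng had no direction. Of 10 BMP and TGF-beta genes, 3 were higher in fibers and 1 in epithelium (median -0.02, percentile 49.5), against 1 and 3 when scaled to housekeeping genes. Id2, an inhibitor of basic helix-loop-helix factors, read 218 in epithelium and 2236 in fibers (10.3-fold). The receptors Bmpr2 and Bmpr1a were 2.90-fold and at least 2.27-fold higher in fibers, and the secreted antagonist Fst was at least 2.60-fold higher in epithelium. Of 9 FGF signalling genes, 3 were higher in fibers and 1 in epithelium (median 0.00, percentile 45.2), against 1 and 3 when scaled to housekeeping genes. That median fell on Etv5, which had no direction and enters it as 0. The feedback inhibitors Spry2 (3.23-fold), Spred2 (at least 2.86-fold) and Spred3 (at least 2.36-fold) were higher in fibers, and the phosphatase Dusp4 was at least 3.17-fold higher in epithelium.

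Of 11 basement membrane genes, 3 were higher in fibers and 2 in epithelium (median -0.04, percentile 37.3). When scaled to housekeeping genes, none was higher in fibers and 4 were higher in epithelium by 2-fold or more. The proteoglycans Hspg2 (perlecan, 510 and 76.7, 6.66-fold) and Agrn (agrin, at least 4.99-fold) were higher in epithelium. The collagen IV chains Col4a2 (2.89-fold), Col4a5 (at least 2.75-fold) and Col4a1 (2.21-fold) were higher in fibers.

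Of 12 autophagy and mitophagy genes, 8 were higher in fibers by 2-fold or more and none in epithelium (median 1.12, percentile 99.7). For 8 of the 12 the ratio was a bound. Gabarapl1, an autophagosome membrane protein, read 282 in fibers and was at least 6.33-fold higher there. Bnip3l, a mitophagy receptor, read 46.6 and 168 (3.59-fold), and Atg5 and Wipi1, which act in autophagosome formation, were at least 2.75-fold and 2.34-fold higher in fibers. With the second brightest probe the median was 0.69, at percentile 97.0, and the list then no longer stood apart. Housekeeping genes lay in the same direction: 10 of 12 had positive log2 ratios, 4 by 2-fold or more, with a median of 0.70 (1.62-fold, percentile 98.5), which by construction was 0.02 when the arrays were scaled to them. The list stood apart under 6 of 12 alternatives. Rab7, a GTPase of late endosomes, was 9.03-fold higher in fibers, Chmp2a at least 3.99-fold and Hprt at least 3.94-fold, while Gapdh read 268 and 546 (2.04-fold). A second probe for Chmp2a gave -1.30, a bound.

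The metabolic and ribosomal lists also had positive medians. Of 6 cholesterol synthesis genes, 3 were higher in fibers and none in epithelium by 2-fold or more (median 1.05, percentile 98.2), and the call ended under 6 of 12 alternatives. Scaled to housekeeping genes, no member reached 2-fold in either direction. The enzymes Lss, Idi1 and Fdps stood at least 2.82-fold, 2.57-fold and at least 1.87-fold higher in fibers, and the sterol sensor Insig1 2.28-fold, but a second Lss probe, above the floor on the fibers array only, had no direction. Of 14 oxidative phosphorylation genes, 4 were higher in fibers and 1 in epithelium (median 0.60, percentile 88.9; median 0.01 when scaled to housekeeping genes). Atp5b, of the ATP synthase, was 3.41-fold higher in fibers, Cox5a at least 3.36-fold and Uqcrc1 at least 2.13-fold, and Uqcrc2 was 3.96-fold higher in epithelium.

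Of 13 glycolysis and hypoxia genes, 4 were higher in fibers and 3 in epithelium (median 0.54, percentile 91.8), and the median was -0.03 when scaled to housekeeping genes. The glucose transporter Slc2a1 read 1322 in epithelium and 294 in fibers (4.51-fold). Pkm, pyruvate kinase (3.87-fold), and Ldha, lactate dehydrogenase A (2.63-fold), were also higher in epithelium, but a second Pkm probe gave 0.71. Vegfa, an angiogenic growth factor (at least 3.50-fold), and the glycolytic enzyme Aldoa (3.41-fold) were higher in fibers. Of 11 ribosomal protein genes, 2 were higher in fibers and none in epithelium (median 0.61, percentile 91.6; median 0.02 when scaled to housekeeping genes), led by Rps15 (3.10-fold), Rps3 (2.44-fold), Rps24 (1.89-fold) and Rps19 (1.81-fold).

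Of 9 RNA-binding proteins studied in lens, 4 were higher in fibers and 1 in epithelium (median 0.84, percentile 92.7; it stood apart with the second brightest probe). Carhsp1 was at least 10.3-fold higher in fibers and Celf1 read 568 and 2127 (3.75-fold), beside Tdrd7 and Caprin2. Igf2bp1 was 2.58-fold higher in epithelium, with a second probe at 0.11. Of 4 immediate early genes, 1 was higher in fibers and 1 in epithelium (median 0.44, percentile 82.9). The phosphatase Dusp1 was at least 10.8-fold higher in fibers and the transcription factor Egr1 at least 3.29-fold higher in epithelium, while Btg2 had a log2 ratio of 0.82 and Ier3 a bound of 0.06.

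**Figure D3:**
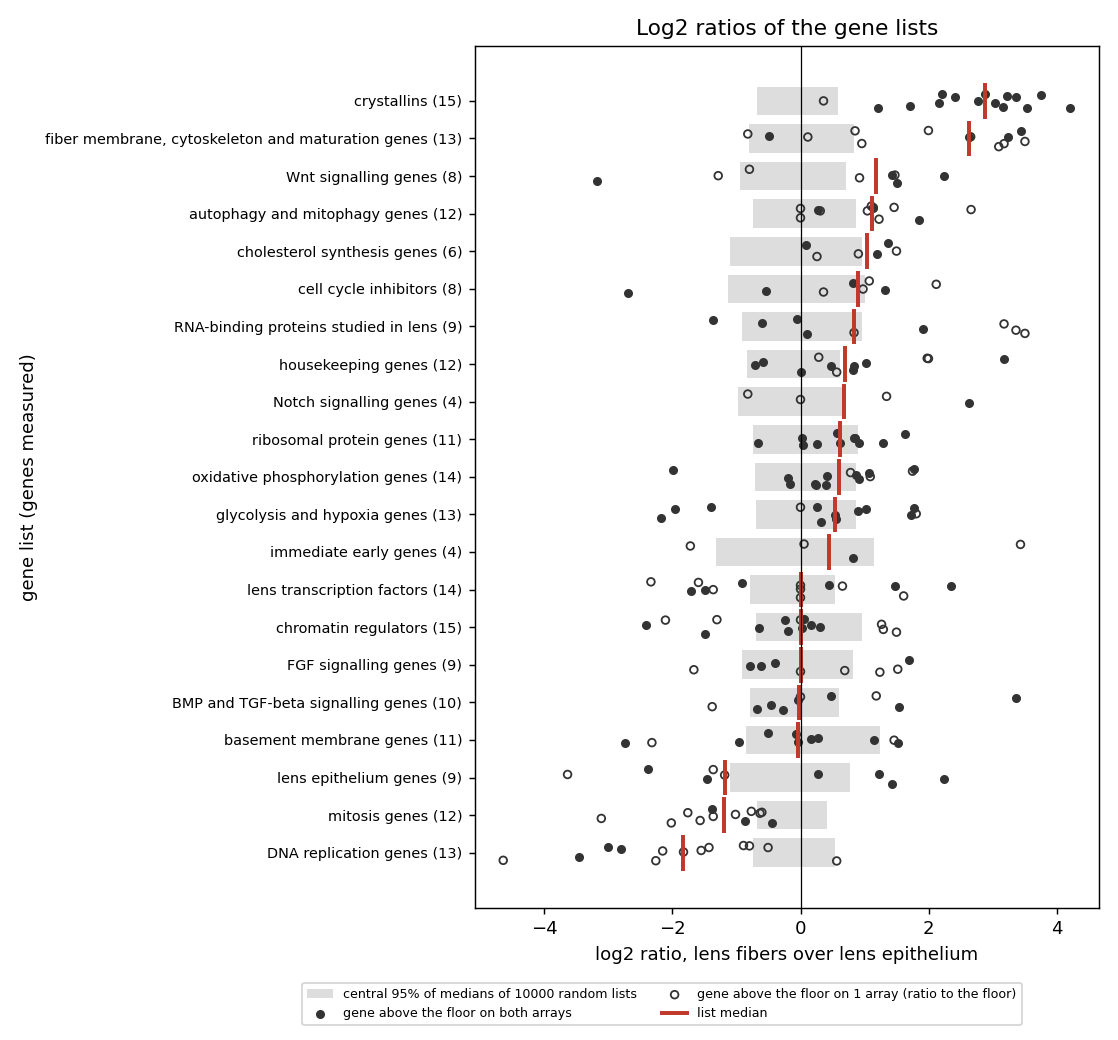
Log2 ratio of lens fibers over lens epithelium (horizontal) for each measured member of the 21 gene lists (vertical, number measured in brackets), with filled points for genes on both arrays, open points for bounds, red bars for list medians and grey bars for the central 95% of medians of 10000 random lists. Of the medians, 6 lie above and 3 below that range, where 1.05 of 21 would by chance. The glycolysis median turned to -0.03 when scaled to housekeeping genes. Genes with no direction are drawn as open points at 0.

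Across all genes, the largest ratios in favour of fibers besides the crystallins and Grifin were those of Irs1, an insulin receptor substrate (82.6 and 1242, 15.05-fold), Ipo8, a nuclear import receptor (13.8-fold), and Dync2h1, a ciliary dynein (10.9-fold). Next came Atp6v1b2, of the vacuolar proton pump (10.8-fold), the growth factor Igf2 (154 and 1640, 10.7-fold) and the surface glycoprotein Cd24a (148 and 1574, 10.6-fold). Chrng, the gamma subunit of the muscle acetylcholine receptor, read 1536 in fibers and was at least 34.4-fold higher. The noncoding RNA Miat (at least 21.7-fold), the cytoskeletal linker Dst (18.6-fold), the connexin Gje1 (15.5-fold) and the spectrin Sptb (13.4-fold) followed as bounds.

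In favour of epithelium, Igfbp5, which binds insulin-like growth factors, read 1612 and 101 (15.9-fold). Mcph1, of chromosome condensation (14.8-fold), the myosin light chain kinase Mylk (14.1-fold), the S-phase kinase Cdk2 (13.7-fold), Sertad2 (11.3-fold), the guidance receptor Robo1 (11.1-fold), Cdca7 (10.98-fold), the lectin Clec2e (10.2-fold) and the RNA-processing factor Zcchc8 (9.79-fold) completed the group with Mcm4. Bounds after Mcm5 were those of Zfp458 (at least 18.3-fold), Copz2 (17.8-fold), Cnot3 (16.9-fold) and Elp2 (16.7-fold), and a second Copz2 probe gave a bound of 0.78. Of the 10 highest ratios in fibers, 9 rest on a single probe, and of the 10 highest in epithelium, 6 had a second probe in the same direction, though much closer to 0 for Mylk (-1.25, a bound), Cdk2 (-0.76) and Robo1 (-0.60, a bound), and at -2.06 for Zcchc8. For Dync2h1, Sertad2, Mcm4, Clec2e and the bounds Zfp458 and Cnot3, all other probes were below the floor on both arrays. So were those of other genes named above, among them Uhrf1, Cdh1, Wnt7b and Rab7.

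The difference has no replicate check. Over 32 silent probes above the floor on both arrays the log2 ratios had a median of -0.49, an SD of 0.84 and a central 95% range of -1.97 to 0.72, and 10 of 32 lay beyond 2-fold. These 32 are the few of 1580 silent probes that exceed both floors, so the range describes a selected set and not silent probes in general. A single 2-fold difference in favour of epithelium is not beyond this range, and one in favour of fibers lies just above it. That contrast between the directions comes with the offset of the range. The floors that selected these probes were unequal, 44.6 on the epithelium array and 32.1 on the fibers array, which moves their ratios toward epithelium. Over all 1580 silent probes the deposited median was 1 on both arrays. The range is thus not centred on 0, and it also depends on the scaling. With arrays centred on their medians it was -1.64 to 1.04, which holds a 2-fold difference in either direction, and after loess -1.89 to 0.83. Counted after the data were examined, 14 of 15 crystallins, 10 of 13 fiber genes and 8 of 12 autophagy genes lay above the range of -1.97 to 0.72, as did 21.4% of all 6490 measured genes. Below it lay 6 of 13 DNA replication genes and 2 of 12 mitosis genes, and 5.04% of all measured genes. Since that range is off centre, the shares above and below it cannot be compared with each other. Of 457 genes with 2 probes on both arrays, 343 (75.1%) had both probes in the same direction, against 50.2% by chance, and of 156 at 2-fold or more, 76 (48.7%) also reached 2-fold with the second probe. Agreement was lower once bounds were included. With probes above the floor on 1 or both arrays, 963 of 1603 genes (60.1%) had the same direction, or none, with both probes. Of 689 such genes at 2-fold or more, 246 (35.7%) also reached 2-fold with the second probe. The balance of the 2-fold counts depended on the scaling and on the floor. Of the genes at 2-fold or more, 45.9% were higher in fibers, against 63.9% with arrays centred on their medians, 60% after loess and 16.1% when scaled to housekeeping genes. The share was 51.8% with the floor at the 75th percentile and 52.7% with the common floor. The median log2 ratio of genes on both arrays was -0.19, and those scalings put it at 0.13, 0.01 and -0.78, while the crystallin, fiber, mitosis and DNA replication lists stood apart under every alternative run.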

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

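The test for fiber RNA carried into the epithelium sample and the comparison of probes at equal brightness were chosen after the result was seen. Of 10378 probes without a gene name here, which entered no comparison above, 2162 were above the floor on at least 1 array. Signal in these unused probes differed between the arrays: of 1042 above the floor on both, 115 were higher on the fibers array by 2-fold or more and 240 were higher on the epithelium array. Probe ILMN_2642375 read 106 in epithelium and 1256 in fibers (11.9-fold) and ILMN_2473066 read 195 and 1678 (8.61-fold), while ILMN_2795698 read 666 and 48.3 (13.8-fold higher in epithelium) and ILMN_1251579 read 460 and 39.3 (11.7-fold). With 1 array per group, there were no further arrays of a group to compare.

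Crystallins and Mip gave signal on the epithelium array at a median of 13.6% of their fibers signal. If carried fiber RNA were the whole source, the shares would be alike within the noise of the arrays and no higher than other bright fiber genes allow, and 6 of 15 exceeded 2 times the 7.58% that is the median share allowed by 13 bright fiber genes below the epithelium floor, a count between those set for and against this explanation. It stays open, although 12 of 15 exceeded even the highest share that any of those 13 genes allows, 8.82%. The lowest of the 15 shares, 5.41% (Crybb1), also exceeded the lowest share allowed, 2.91% (Chrng). Those 13 genes were picked for being below the floor, so probe noise can make the shares they allow too low. With 1 array per group that noise was not measured. Compression of ratios at bright probes also stays open, with a Spearman rho of -0.10 between fibers intensity and log2 ratio across these genes, between the limits set for and against it. Crystallin expression by epithelial cells themselves was not tested.

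Housekeeping genes were higher on the fibers array, with a median log2 ratio of 0.70, and the list stood apart under 6 of 12 alternatives. Whether the scaling between the arrays is the cause cannot be told apart from a difference of these genes between the tissues. The median of 272 genes outside all lists whose 2 brightest probes lay within 2-fold of each other was -0.077, but quantile normalization holds most genes near 0 whatever the true scaling, so the limit set for this value could not decide. A difference between the tissues was not tested.

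Many of the brightest probes carried names of genes whose other probes were dim. Among the 100 brightest genes with several probes, 74% (74 of 100, exact 95% interval 64.3 to 82.3) had a second probe over 8-fold dimmer, against 17.6% (3 of 17, 3.80 to 43.4) of ribosomal, oxidative phosphorylation, housekeeping and crystallin genes. The 100 were picked for a bright probe and the 17 were not, which favours a gap, and of the 8 that were as bright as the 100, a comparison added after seeing the data, 1 had such a gap (exact 95% interval 0.316 to 52.7). Both intervals lie below that of the 100, and both shares are more than 15 percentage points lower, the limit written before the comparison with the 17. This argues against ordinary differences between probes of abundant transcripts as the whole cause. For the 8, a minimum of 10 genes had first been required, and it was dropped after the result was seen because the written prediction held no minimum, so that comparison carries less weight. Binding to other transcripts stays open and was not tested, since probe sequences were not used here. Rchy1, chosen after its values were seen, read 19878 and 15182, with a second probe at -1.15 and 52.2, and no biological explanation was tested.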

How the results depend on the processing

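The scaling to housekeeping genes and the common floor were chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Across all alternatives, the crystallin (2.29 to 3.21), fiber (1.81 to 3.02), mitosis (-1.78 to -0.76) and DNA replication (-2.43 to -0.997) medians kept their direction and their place outside the central 95% of random lists. Autophagy kept its place in 11 of 12, lens epithelium and Wnt in 7, and cholesterol and housekeeping in 6. Lists inside the central 95% left it upward in 2 of 12 for cell cycle inhibitors, 3 for Notch and 1 for RNA-binding proteins. Of 253 list medians under alternatives, 194 moved by less than the SD of random lists, and of 1651 values for 141 named genes, 1475 moved by less than the SD of the silent probes. Genes with a single probe count as unmoved under the mean of all probes and under the second brightest probe. Signal over background limits the dim genes: 12567 of 19057 were below both floors. Where no reason is given, the cause was not tested.

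The counts of genes higher in fibers and in epithelium, 1006 and 1186, were 2525 and 2584 with the floor at the 60th percentile, 4592 and 3886 with no floor, 524 and 568 with an offset of 50, which shrinks ratios by construction, 660 and 751 with the mean of all probes, 585 and 611 with the second brightest probe, for which fewer genes have a value, 450 and 2346 when scaled to housekeeping genes, 1604 and 1997 at 1.5-fold and 228 and 311 at 4-fold. With the floor at the 75th percentile they were 1698 and 1581, and with the common floor 1003 and 901.

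With arrays centred on their medians, the list medians were 3.21 for crystallins, -0.87 for mitosis and -1.51 for DNA replication, and after loess -0.84 for mitosis. With the floor at the 60th percentile they were 3.02 for fiber genes, -2.31 for DNA replication, -0.0041 for Wnt, a change of sign, and 0.024 for RNA-binding proteins. With the floor at the 75th percentile they were 0.45 for lens transcription factors, 0.95 for FGF, 0.48 for cholesterol and 0.10 for RNA-binding proteins. With no floor they were -1.24 for DNA replication, 0.00 for Wnt, 0.090 for cholesterol and 0.024 for RNA-binding proteins.

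With an offset of 50 they were 1.81 for fiber genes, -0.58 for lens epithelium, -0.76 for mitosis, -0.997 for DNA replication, 0.69 for Wnt and 0.67 for autophagy. With the mean of all probes they were 2.17 for fiber genes, 0.00 for lens epithelium, 0.042 for Wnt, 1.34 for Notch and 0.21 for cholesterol. With the second brightest probe they were 2.09 for lens epithelium, 0.44 for lens transcription factors, -1.30 for DNA replication, 0.92 for FGF, 0.41 for BMP and TGF-beta, 0.63 for Wnt, 1.34 for Notch, 0.69 for autophagy, 0.17 for cholesterol and 1.98 for RNA-binding proteins. The sign for lens epithelium reversed because 4 of 9 members fell out, 5 were left and none of these changed sign. Its size is that of Sparc, which was at 0.27 with its brightest probe and 2.09 with its second. With the second brightest probe Copz2 (0.78), Pkm (0.71), Igf2bp1 (0.11) and Chmp2a (-1.30) reversed.

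Scaled to housekeeping genes, which lowers ratios by construction, they were 2.29 for crystallins, 1.99 for fiber genes, -1.78 for lens epithelium, -1.78 for mitosis, -2.43 for DNA replication, 0.30 for cell cycle inhibitors, -0.38 for BMP and TGF-beta, 0.59 for Wnt, -0.65 for basement membrane, 0.51 for autophagy, -0.033 for glycolysis, 0.47 for cholesterol, 0.0062 for oxidative phosphorylation, 0.025 for ribosomal proteins, -0.56 for chromatin regulators, 0.24 for RNA-binding proteins and 0.021 for housekeeping genes. With the common floor they were -0.71 for lens epithelium, -0.89 for lens transcription factors, -0.87 for mitosis, -1.35 for DNA replication and 1.34 for Notch.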

Other observations

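The test in this part was set before its result was seen, and the genes named were chosen after their values were seen. Genes were grouped by the letters that begin their symbols, giving 60 groups of at least 10 measured genes. The Ndufa genes, which encode subunits of respiratory complex I, had 10 of 11 positive log2 ratios, 4 of them at 2-fold or more in fibers (median 0.84, percentile 99.6, and 0.24 with 7 of 11 positive when scaled to housekeeping genes). Ndufa13 read 114 in epithelium and 428 in fibers (3.76-fold) and Ndufa10 read 65.9 and 204 (3.10-fold). Genes beginning with Atp, mostly subunits of ion pumps and of the ATP synthase, had 33 positive log2 ratios of 41, 14 at 2-fold or more in fibers and 3 in epithelium (median 0.58, percentile 99.9, and 0.00 with 20 of 41 positive when scaled to housekeeping genes). Atp6v1d, of the vacuolar proton pump, was at least 3.30-fold higher in fibers and Atp6v1e1 2.49-fold, while Atp6v0b read 59.5 and 34.2 (1.74-fold higher in epithelium).

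The hypothesis that gene families beyond the fixed lists differ together was not settled. Of the 60 groups, 2 lay outside the central 99% of random lists, where 0.6 would by chance, and chance gives as many in 12.1% of cases. Both groups share members with the oxidative phosphorylation list, and housekeeping genes lay in the same direction.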
